A study of Mus musculus with 16 samples.

How the data were processed

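Ear skin RNA of C57BL/6 mice was measured by RNA sequencing of polyA RNA. The labels describe 16 libraries in 4 groups: 5 of control ears, 5 of ears given MC903, 3 of MC903 with an antibody against oncostatin M (anti-OSM) and 3 of MC903 with an antibody against Ly6G (anti-Ly6G). MC903 is calcipotriol, a vitamin D analogue that induces inflammation resembling atopic dermatitis. The deposited table used here holds the 6 antibody libraries; the other 10 libraries were not analysed here, so the comparisons planned against control and MC903 ears, and the overlaps between them, were not run. Per the labels' protocols, the antibody groups received 50 µM MC903 in a volume of 20 µL on both ears daily for 10 days. Anti-OSM was injected into the skin every other day at 20 µg per mouse. Anti-Ly6G was injected into the peritoneum at 200 µg per mouse 2 days before and 1 and 4 days after MC903. Antibody, route and schedule therefore differed together, and no isotype antibody is named for these groups. The labels used here give no day of collection or library batch. A batch difference between the groups therefore cannot be told apart from the antibodies.

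The deposited table gives, per the file headers, a read count, an FPKM and a TPM value for each gene and library. The read counts as deposited are whole numbers, and how reads were assigned to genes and whether strand was used is not given in the sources used here. The FPKM values were deposited by the authors and were used only to check the columns. The TPM values, per the file headers, summed to 1000000 in each library and were likewise used only as a check. The submitters' processing notes name bcl2fastq 2.20.0, Trimmomatic 0.38, HISAT2 2.1.0, SAMtools 1.9, StringTie 2.1.3b and edgeR 3.40.2 with no roles, and builds that include mm10. Gene positions are from the RefSeq annotation of GRCm38.p6, the assembly that mm10 names.

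Genes were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM scaling, robust quasi-likelihood fits and 2-sided F-tests with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit held the 6 libraries with no covariate. Fold changes are log2 of anti-OSM over anti-Ly6G, so positive values are higher with anti-OSM. Standard errors were derived from the fold change and its F statistic, and CPM values use TMM-scaled library sizes. The labels do not state that replicates came from separate mice, so p-values measure the spread between these libraries. Libraries of a group differed beyond counting noise, with a chi-square per gene of at least 26.2 over genes with more than 100 counts in the pair, so none was treated as a duplicate.

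The 39 gene lists and the rule for named genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it, adjusted over the 39 lists. The 7 lists written after the values were seen were adjusted over those 7 only. Named genes are the 6 with the largest and the 6 with the smallest log2 fold change among called genes with at least 10 CPM in the higher group and no overlap between groups, gene models left out. Up to 4 members of each list with the smallest p, and a fixed set of oncostatin M, neutrophil, type 2, vitamin D and barrier genes, were added whatever their p. Any other gene is named as chosen after its values were seen.

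On counts simulated from the 6 libraries for this comparison, 19572 genes were tested. Of 50 genes changed 1.5-fold 32.0% were recovered, 76.0% at 2-fold, 94.0% at 4-fold and 96.0% at 8-fold. Of the 160 calls 6.88% were false. The simulation changed 200 genes and drew each gene independently, while 2406 genes were called in the data. These rates may therefore differ from those in the data. Alternatives were other scalings, DESeq2 1.42.0, limma-voom, other filters, a non-robust fit, a 2-fold threshold, leaving out each library, a replicate block and scaling without tissue-list genes. Total counts of 52163179 to 64122588 set a floor of 3 counts at 0.0468 to 0.0575 CPM. Intervals and floors cover the errors named only.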

Results

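Transcripts of MC903-treated mouse ear skin were compared between 3 libraries of mice given anti-OSM, for oncostatin M neutralisation, and 3 given anti-Ly6G, an antibody against a neutrophil surface protein. Total counts were 52163179, 59063578 and 57479602 in the anti-OSM libraries and 61952450, 59381146 and 64122588 in the anti-Ly6G libraries. Of 45777 listed genes, 16043 had no count and 19915 were tested. The first principal component held 43.6% of the variance and parted the groups, and anti-Ly6G replicate 3 (14.9) lay nearer the anti-OSM libraries than replicates 1 (38.6) and 2 (39.3).

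The comparison asked how skin of mice given anti-OSM differed from skin of mice given anti-Ly6G. Neutralisation and depletion themselves were not tested, since ears given MC903 alone were not analysed here. Falls and rises are of anti-OSM relative to anti-Ly6G throughout, and which group moved cannot be told. With anti-OSM, the epithelial cytokine genes Il24 and Tslp, activated keratinocyte genes and the vitamin D target Cyp24a1 were lower, while markers of eosinophils, mast cells, macrophages and dendritic cells were higher. Skeletal muscle, cartilage and cholesterol synthesis genes were lower, and clock genes moved in both directions. Of 39 gene lists, camera called 10 higher and 10 lower with a preset correlation, and 0 with an estimated correlation (lowest adjusted p = 0.0605). Fry's directional test called 6 lists, and those of eosinophils, macrophages, dendritic cells and activated keratinocytes were not among them. In edgeR's quasi-likelihood test, 1157 genes were higher and 1249 lower with anti-OSM, and 17509 did not pass. Of these, 157 higher and 235 lower genes differed by at least 2-fold. Leaving out 1 library moved the counts by more than 1.5 times for every library but anti-Ly6G replicate 3: to 290 higher and 420 lower without anti-OSM replicate 1, 462 and 515 without replicate 2, 240 and 464 without replicate 3, 457 and 615 without anti-Ly6G replicate 1, and 580 and 739 without replicate 2.

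**Figure D1:**
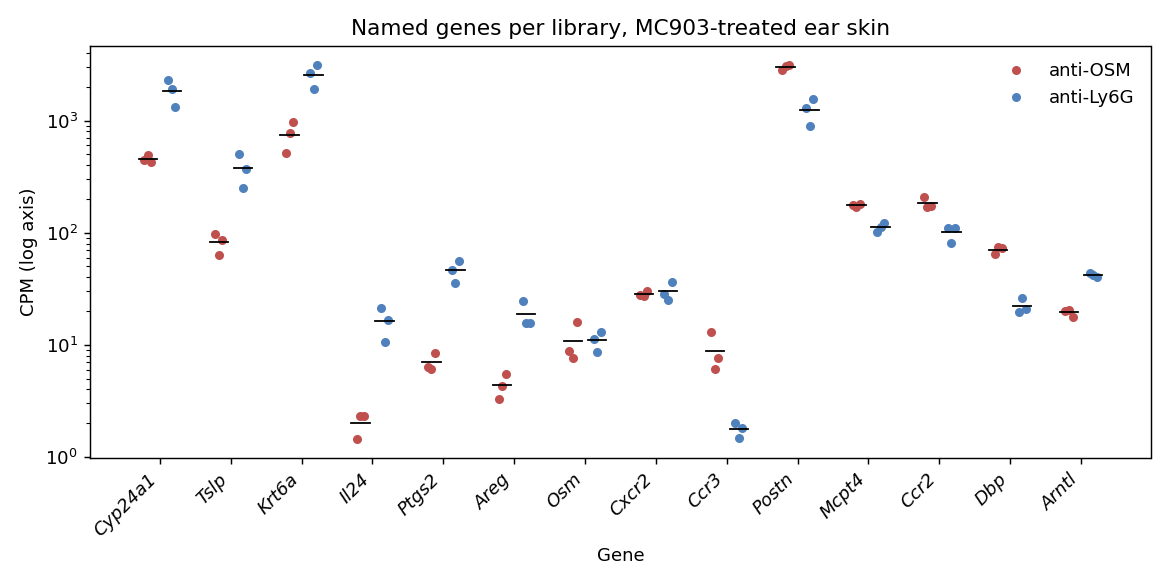
CPM (log axis) of 14 named genes in each of the 3 anti-OSM and 3 anti-Ly6G libraries; points are libraries and bars are group means. Cyp24a1 and Tslp lay lower in every anti-OSM library and Ccr3 and Postn higher, while Osm and Cxcr2 overlapped.

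Among the largest falls with anti-OSM were Il24, a cytokine of the IL-20 family (gene ID 93672, chromosome 1, 130882074 to 130887411, GRCm38), at 2.03 ± 0.499 CPM against 16.2 ± 5.29 (SD, n = 3), a log2 fold change of -2.99 (SE 0.29, adjusted p = 0.00272). Ptgs2, which encodes the inducible cyclooxygenase, had -2.73 (SE 0.20, adjusted p = 0.00107), and Gprc5a -2.98 (SE 0.25, adjusted p = 0.00215). Mmp13, a collagenase, fell by 2.74 on the log2 scale, Lrat, a retinol esterifying enzyme, by 2.33, and Epgn, an EGF receptor ligand, by 2.32. Of the largest rises, Dbp (1.67, SE 0.12, adjusted p = 8.89e-04) and Mid1 (1.72, SE 0.13, adjusted p = 9.85e-04) kept their calls without each library, as did Erdr1 (1.82, SE 0.27). Mid1 and Erdr1 lie side by side near the end of the X chromosome, where near-identical copies can share reads, so both are uncertain. F5 (1.96), Ccl24 (1.62) and Siglecg (1.58) also passed. F5 lost its call without anti-OSM replicate 3 or anti-Ly6G replicate 1 or 2 (adjusted p 0.0725 to 0.0855), Ccl24 without those or anti-OSM replicate 1 (0.0582 to 0.0892), and Siglecg without any 1 of the 6 libraries (0.0539 to 0.0995). With no filter on low counts, Ccl24 (adjusted p = 0.0600) and Siglecg (0.0806) did not pass.

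The genes of oncostatin M and its receptor did not pass the test, and Ly6g lay near the floor. Osm was at 10.8 ± 4.56 CPM with anti-OSM and 10.97 ± 2.22 with anti-Ly6G, a log2 fold change of -0.02 (95% interval -0.71 to 0.67, adjusted p = 0.973). Its receptor gene Osmr had -0.22 (-0.41 to -0.02, adjusted p = 0.133) and the shared subunit gene Il6st 0.11 (-0.06 to 0.27). Ly6g had 3, 0 and 0 counts with anti-OSM and 3, 3 and 3 with anti-Ly6G, at or under the floor of 3 counts, so no fold is given. Cxcr2, a neutrophil chemokine receptor, had -0.08 (-0.38 to 0.23), S100a8 -0.10 (-0.94 to 0.75) and S100a9 0.04 (-1.04 to 1.12). Of 20 measured neutrophil markers 0 were higher, 2 lower and 18 did not pass (0 and 1 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.276). With all 6 libraries the main test called no neutrophil marker lower with anti-Ly6G than with anti-OSM. The 2 called, Padi4 (-1.30) and Trem1 (-1.03), were higher with anti-Ly6G. Retnlg, also of that list, went the other way at 2.06 (adjusted p = 0.112), with no overlap between groups, as in 35.0% of all tested genes. Retnlg passed in DESeq2 (adjusted p = 0.0302). In edgeR it did not pass without each library in turn (adjusted p 0.0560 to 0.272). Without anti-Ly6G replicate 3, 1 neutrophil marker, not Retnlg, was called higher with anti-OSM and 1 lower. Trem1 lost its call without any 1 of the 6 libraries (adjusted p 0.0538 to 0.118) and Padi4 without any but anti-Ly6G replicate 3 (0.0528 to 0.106). The oncostatin M and gp130 family had 2 higher and 2 lower of 20 (3 and 3 adjusted over the list alone; camera adjusted p = 0.888), and 0 or 1 higher and 1 lower without each library.

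The alarmin genes Tslp and Il33 and the vitamin D target Cyp24a1 were lower with anti-OSM. Tslp (chromosome 18, 32815383 to 32819799) was at 82.2 ± 17.7 CPM against 374 ± 127, a log2 fold change of -2.19 (SE 0.28, adjusted p = 0.00872), and Il33 had -0.81 (adjusted p = 0.0151). The Il33 call was lost without anti-OSM replicate 1 or 2 or anti-Ly6G replicate 1 (adjusted p 0.0566 to 0.0603). Their list, type 2 cytokines, alarmins and their receptors, had 1 higher (Il5ra), 2 lower and 11 not passing of 14 (4 and 2 adjusted over the list alone) and did not pass camera (adjusted p = 0.660, median log2 fold change 0.15). Cyp24a1, which degrades active vitamin D (chromosome 2, 170482957 to 170497145), was at 456 ± 37.1 CPM against 1846 ± 491 (-2.02, SE 0.19, adjusted p = 0.00247). It was the 1 called member of 10 in the vitamin D list (0 higher and 2 lower adjusted over the list alone), which was lower in camera (adjusted p = 0.00699; adjusted p = 0.530 with an estimated correlation). That list call was lost without anti-OSM replicate 1 (adjusted p = 0.0545) or anti-Ly6G replicate 2 (0.0504). Its members Hr (-0.52, adjusted p = 0.0602) and S100g (-1.15, adjusted p = 0.0945) did not pass. Neither overlapped between groups, which held for 35.0% of all tested genes. Both passed in DESeq2 (adjusted p = 0.00398 and 0.0105). Both also passed in edgeR without anti-Ly6G replicate 3 (adjusted p = 0.0183 and 0.0121), where 3 members of the list were lower. The receptor gene Vdr had -0.23 (adjusted p = 0.145). Il4 (0.08, adjusted p = 0.945), Il13 (0.86, adjusted p = 0.0969) and Il1rl1 (0.58, adjusted p = 0.0692) did not pass. Without anti-Ly6G replicate 3, Il13 (adjusted p = 0.0204) and Il1rl1 (0.00415) passed, and 4 members of the type 2 cytokine list were higher. Il31 had 6 counts in 1 anti-OSM library and 0 in the others, and Il17a had 0 in all 6.

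Activated keratinocyte and antimicrobial genes were lower as a list: 10 of 31 were lower, 0 higher and 21 did not pass (14 lower adjusted over the list alone; camera adjusted p = 1.75e-09, and adjusted p = 0.530 with an estimated correlation). Without each library, 6 (anti-OSM replicate 2) to 12 (anti-OSM replicate 3) were lower. A list of 18 keratinocyte lineage genes, written after the values were seen, had 0 higher and 5 lower. Its camera adjusted p was 3.41e-05, and 0.248 with an estimated correlation, adjusted over the 7 lists so written and not over the 39. Krt6a, a keratin of stressed epidermis, was at 750 ± 227 CPM against 2573 ± 606 (-1.78, SE 0.26, adjusted p = 0.0111), and Gjb6 (-1.29), Sprr1a (-1.09) and Slpi (-1.01) also fell. Krt16 had -0.86 (adjusted p = 0.0950); it passed without anti-OSM replicate 3 (adjusted p = 0.0279). The cornified envelope list had 1 higher and 8 lower of 44 (6 and 12 adjusted over the list alone) and did not pass camera (adjusted p = 0.834). Its median log2 fold change was 0.11 and its mean -0.08, and it was called higher without anti-Ly6G replicate 1 (adjusted p = 0.0178), with 14 higher and 1 lower. It had 0 lower without anti-OSM replicate 1 and 1 without replicate 2 or 3. Flg had 0.02 (-0.24 to 0.27) and Lor 0.27 (-0.19 to 0.73).

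Markers of eosinophils, mast cells and antigen-presenting cells were higher with anti-OSM. Of 10 eosinophil markers 4 were higher and 0 lower (7 higher adjusted over the list alone; camera adjusted p = 6.13e-09, and adjusted p = 0.417 with an estimated correlation). Ccr3, the eotaxin receptor gene, was at 8.88 ± 3.56 CPM against 1.76 ± 0.266 (2.33, SE 0.29, adjusted p = 0.00499), and Il5ra had 2.07. Mast cell markers had 6 of 15 higher (13 adjusted over the list alone; camera adjusted p = 9.25e-10, and adjusted p = 0.395 with an estimated correlation), among them the protease genes Mcpt4 (0.65), Cma1 (0.79) and Cpa3 (0.87). Macrophage and monocyte markers had 8 of 25 higher (14 adjusted over the list alone; camera adjusted p = 9.38e-10, and adjusted p = 0.530 with an estimated correlation), with Ccr2 at 0.86. Dendritic and Langerhans markers had 12 higher and 1 lower of 20 (14 and 1 adjusted over the list alone; camera adjusted p = 2.46e-09, and adjusted p = 0.449 with an estimated correlation), with Mgl2 at 0.83 and Cd209a at 1.11. Type 2 chemokine and effector genes had 8 higher and 1 lower of 21 (11 and 2 adjusted over the list alone; camera adjusted p = 3.00e-08, and adjusted p = 0.382 with an estimated correlation). Postn, a matrix protein gene, had 1.28 (adjusted p = 0.00720), while Areg, an EGF receptor ligand, fell by 2.09. Without each library, 2 (anti-Ly6G replicate 1) to 6 eosinophil, 5 to 9 mast cell, 3 (anti-OSM replicate 3) to 17 macrophage, 4 (anti-OSM replicate 2 or 3) to 14 dendritic and 4 (anti-Ly6G replicate 1) to 12 type 2 effector genes were higher. All these counts but that of eosinophil markers, which was highest without anti-OSM replicate 2, were highest without anti-Ly6G replicate 3.

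T cell markers had 2 of 24 higher, Trac (0.61) and Cd4 (1.16) (2 adjusted over the list alone; camera adjusted p = 1.68e-05, and adjusted p = 0.580 with an estimated correlation). That count was 13 without anti-Ly6G replicate 3 and 0 without any other library, where Trac had an adjusted p of 0.0554 to 0.0833 and Cd4 of 0.0538 to 0.0947. B cell and plasma cell markers had 2 of 9 higher (2 adjusted over the list alone; camera adjusted p = 0.00535, and adjusted p = 0.530 with an estimated correlation), Cd79b (1.52) and Ighm (1.24). Fibroblast and dermal matrix genes had 9 higher and 1 lower of 20 (11 and 1 adjusted over the list alone; camera adjusted p = 1.05e-04, and adjusted p = 0.551 with an estimated correlation), and Mfap4 had 0.53 and the elastin gene Eln -0.49. Without anti-OSM replicate 1 or 2, 1 fibroblast gene was higher, 2 without replicate 3, 3 without anti-Ly6G replicate 1, 4 without replicate 2 and 11 without replicate 3. Mitochondrially encoded genes had 2 of 13 higher (12 adjusted over the list alone; camera adjusted p = 1.11e-05, and adjusted p = 0.551 with an estimated correlation), and their share of counts was 3.64% to 4.10% with anti-OSM and 2.88% to 3.47% with anti-Ly6G. Without anti-Ly6G replicate 1, 10 of them were higher, 1 without replicate 3 and 0 without any other library.

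**Figure D2:**
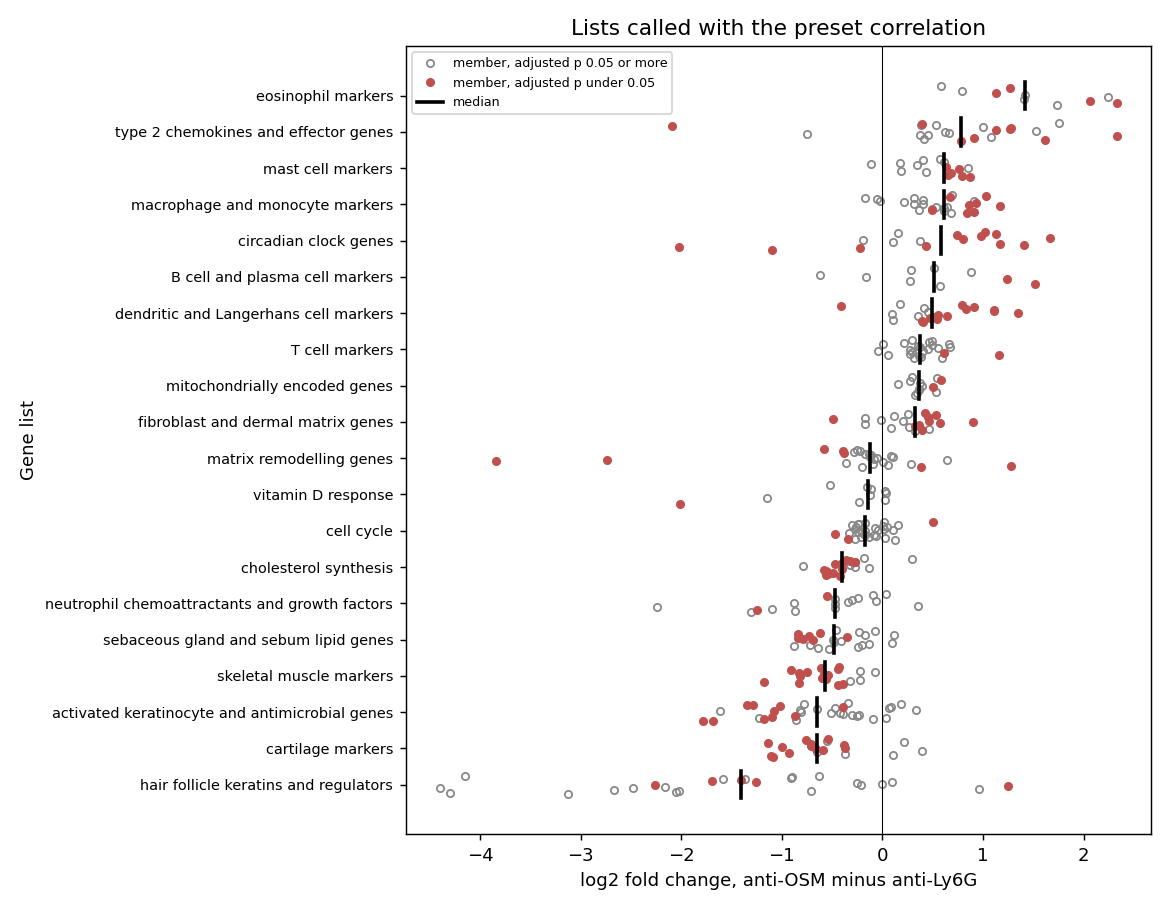
The log2 fold change (anti-OSM minus anti-Ly6G) of each member of the 20 lists called by camera with the preset correlation; filled points passed the gene test and bars are list medians. Medians ran from -1.41 in hair follicle genes to 1.42 in eosinophil markers, and 0 of the lists held with an estimated correlation.

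Skeletal muscle, cartilage, cholesterol synthesis, sebaceous and hair follicle lists were lower with anti-OSM in camera, while barrier lipid, nerve and adipocyte lists did not pass. Skeletal muscle markers had 16 of 20 lower (18 adjusted over the list alone; camera adjusted p = 2.44e-22, and adjusted p = 0.382 with an estimated correlation), with Myh4, a fast myosin gene, at -1.18 (SE 0.10, adjusted p = 0.00125) and Ckm at -0.82. Cartilage markers had 13 of 19 lower (16 adjusted over the list alone; camera adjusted p = 2.87e-15, and adjusted p = 0.0605 with an estimated correlation), with the collagen genes Col9a2 at -1.00 and Col9a3 at -0.71. Cholesterol synthesis genes had 15 of 21 lower (18 adjusted over the list alone; camera adjusted p = 1.69e-12, and adjusted p = 0.395 with an estimated correlation), among them Fdft1 (-0.55) and Sqle (-0.49). Sebaceous genes had 7 of 23 lower (9 adjusted over the list alone; camera adjusted p = 2.76e-06, and adjusted p = 0.530 with an estimated correlation), with Acaca at -0.73 and Fasn at -0.84. Hair follicle genes had 1 higher and 4 lower of 25 (1 and 4 adjusted over the list alone; camera adjusted p = 1.99e-04, and adjusted p = 0.636 with an estimated correlation), with Tchh at -2.26 and Hoxc13 at -1.26. Epidermal barrier lipid synthesis genes had 3 higher and 2 lower of 26 (3 and 3 adjusted over the list alone, camera adjusted p = 0.937), and 1 to 3 higher and 2 to 4 lower without each library. Schwann cell and nerve markers had 2 higher and 2 lower of 12 (2 and 2 adjusted over the list alone, camera adjusted p = 0.744), and 0 to 1 higher and 0 to 2 lower without each library. Adipocyte markers had 0 higher and 4 lower of 15 (0 and 4 adjusted over the list alone; camera adjusted p = 0.104) and were called lower without anti-Ly6G replicate 1 (adjusted p = 0.0139). Without each library, 8 (anti-OSM replicate 1) to 15 muscle, 9 to 12 cartilage, 5 (anti-OSM replicate 2 or 3) to 15 cholesterol, 2 (anti-Ly6G replicate 2) to 8 sebaceous, 2 (each anti-OSM library) to 20 hair follicle (anti-Ly6G replicate 3) and 1 to 2 adipocyte genes were lower.

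Clock genes had 9 higher and 3 lower of 16 (10 and 3 adjusted over the list alone; camera adjusted p = 1.61e-08, and adjusted p = 0.395 with an estimated correlation). Dbp (1.67), Per2 (1.41) and Nr1d2 (0.80) were higher, and the activator Arntl was lower, at 19.5 ± 1.496 CPM against 41.7 ± 1.74 (-1.10, SE 0.08, adjusted p = 9.85e-04).

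Neutrophil chemoattractants and growth factors had 0 higher and 2 lower of 17 (0 and 2 adjusted over the list alone; camera adjusted p = 0.00176, and adjusted p = 0.530 with an estimated correlation). The 2 called were Ltb4r1, a leukotriene receptor gene, at -0.55 and Cxcl3 at -1.25 (adjusted p = 0.0158). The Cxcl3 call was lost without anti-OSM replicate 1 or 2 or anti-Ly6G replicate 1 (adjusted p 0.0564 to 0.0610). Cxcl1 (-1.30, adjusted p = 0.350), Cxcl2 (-0.87), Csf3 (-2.25, adjusted p = 0.105) and Il1b (-0.88) did not pass. Matrix remodelling genes had 2 higher and 5 lower of 25 (3 and 5 adjusted over the list alone; camera adjusted p = 0.0344, and adjusted p = 0.636 with an estimated correlation), with Mmp10 at -3.84 and Sdc1 at -0.58; Mmp9 had 0.01 (-0.44 to 0.45). That list call was lost without anti-OSM replicate 2 (adjusted p = 0.116) or anti-Ly6G replicate 3 (0.326). Cell cycle genes had 1 higher and 2 lower of 30 (1 and 2 adjusted over the list alone; camera adjusted p = 0.0344, and adjusted p = 0.729 with an estimated correlation), a call lost without anti-OSM replicate 1 (0.340) or anti-Ly6G replicate 1 (0.194) or 3 (0.0941). The other 19 lists did not pass camera. Interferon response genes had 1 higher of 31 (0 adjusted over the list alone; median log2 fold change -0.07, mean -0.09, camera adjusted p = 0.937 with the direction higher). The itch list had 3 higher and 6 lower of 30 (3 and 7 adjusted over the list alone; camera adjusted p = 0.116) and was called lower without anti-OSM replicate 3 (0.0247) or anti-Ly6G replicate 1 (0.0185) or 2 (0.0122). The IL-17, IL-22, IL-23 and IL-36 cytokine list had 1 higher and 2 lower of 13 (2 and 3 adjusted over the list alone; median log2 fold change 0.11, mean -0.24, camera adjusted p = 0.410) and was called lower without anti-Ly6G replicate 2 (0.0122). These small counts changed without most libraries: 0 to 3 interferon response genes and 0 to 5 itch genes were higher, 4 to 6 itch genes and 1 to 3 of the IL-17 list were lower, and 0 to 3 cell cycle, 3 to 6 matrix remodelling and 1 to 2 chemoattractant genes were lower. In fry's directional test, 6 lists passed: cartilage, skeletal muscle, cholesterol synthesis, type 2 chemokine and effector, mast cell and clock genes. The eosinophil (fry adjusted p = 0.0821), dendritic (0.0821), macrophage (0.111) and activated keratinocyte (0.128) lists did not pass it. Neither did any other list that camera called.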

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

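The alternatives were planned, except scaling without tissue-list genes for the gene lists, which was chosen after seeing the data. Counts of higher and lower genes stayed within 1.5 times of 1157 and 1249 under both other scalings, DESeq2 (1655 and 1746), limma-voom, both other filters, the non-robust fit and scaling without tissue-list genes. A 2-fold threshold left 157 and 235, by its construction. Leaving out each library gave 240 to 1545 higher and 420 to 1447 lower genes; fewer libraries lower the power, and only without anti-Ly6G replicate 3 did both counts rise, and the cause was not tested. The replicate numbers are shared between groups but not stated to mark a litter or day. Deviations of same-numbered libraries correlated at 0.0116 to 0.124, not all over 0.1, and 4 of 6 libraries correlated best with their own number. With the replicate block 1325 genes were higher and 1275 lower. Of the named genes, 16 gained a call, among them Retnlg (adjusted p = 0.00272), Il1b (0.0140) and Krt16 (0.0413), and 4 lost it. The itch list gained a call (adjusted p = 0.00337) and the cell cycle list lost its call (adjusted p = 0.0514). Of 115 called named genes, 61 kept their call without each library and 54 lost it at least once, and 0 named genes reversed. Of 20 called lists, 17 held without each library; 0 held with an estimated correlation and 14 were lost with fry. For the cornified envelope list, camera's direction turned from lower to higher without anti-Ly6G replicate 1 (adjusted p = 0.0178), while its median log2 fold change was 0.11 with all 6 libraries, 0.12 without that one and 0.0140 to 0.135 over the libraries left out; the cause was not tested. A fit of all 16 libraries, and every alternative of the comparisons with control or MC903 ears, was not run. Ly6g, Il31 and Il17a lie near or under 3 counts, so no change in them could be measured, and whether depth is the cause was not tested.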

Other observations

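The lists in the next sentences were written after the values were seen, and so were all tests of this part but that of other splits. The p-values of these lists were adjusted over the 7 lists so written, some of them parts of others. They do not compare with p-values adjusted over the 39 lists. Amino acid response and serine synthesis genes were lower with anti-OSM: 25 of 30 fell and 0 rose (26 adjusted over the list alone). Asns, Mthfd2 and Cth prompted the list; without them, 22 of 27 fell (camera adjusted p = 1.18e-21, and adjusted p = 0.0257 with an estimated correlation). Asns had a log2 fold change of -1.01 (SE 0.10) and Cth -1.50 (SE 0.15). Retinoid genes, prompted by Lrat and Crabp2, had 3 of the remaining 19 lower (camera adjusted p = 0.0485, and adjusted p = 0.128 with an estimated correlation). EGF receptor ligands and targets, prompted by Areg and Epgn, had 1 of the remaining 12 lower and did not pass (camera adjusted p = 0.151).

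The next genes were chosen after their values were seen. AY036118 had 236, 238 and 240 counts with anti-OSM and 0 in each anti-Ly6G library, at least 79.8-fold higher against a floor of 3 counts per library; it overlaps the ribosomal RNA pseudogene Rn18s-rs5 on chromosome 17 (39848112 to 39898385, GRCm38). Gm42031 had 7, 17 and 10 counts against 1060, 797 and 1005. How the reads of AY036118 and Gm42031 map, and the genotype of the mice at these genes, were not checked, so both differences are uncertain. Ecel1 had 0.917 ± 0.132 CPM with anti-OSM and 9.88 ± 1.29 with anti-Ly6G (SD, n = 3).

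Clock genes differed between the groups. The median log2 fold change of the 3 activators was -1.10 (SE of members 0.52) and that of the 12 repressors and outputs 0.89 (0.16), and 3 activators are too few to exclude different shares of cell types. A different time of day at collection stays open too: of Usp2, Wee1 and Nfil3, 1 gene moved with its phase by more than 2 SE, Wee1 (0.64, SE 0.14), while Usp2 moved against it (-0.36, SE 0.07). An effect of the antibodies themselves was not tested, and collection times are not among the labels used here.

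Cyp24a1 and Tslp were lower with anti-OSM. A lower share of keratinocytes would lower their lineage genes alike, and the tables argue against that as the whole cause: the median of 18 lineage genes was -0.28 (SD of members 0.33), above the upper 95% limits of Cyp24a1 (-1.58) and Tslp (-1.51). That list was itself lower in camera (0 higher and 5 lower; adjusted p = 3.41e-05, and adjusted p = 0.248 with an estimated correlation), so a smaller part of the fall stays open. Weaker exposure to MC903 cannot be told apart from an antibody effect. Of 10 vitamin D response members, 1 was called lower with all 6 libraries and 3 without anti-Ly6G replicate 3. No ears without MC903 were analysed here to show which members respond.

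Skeletal muscle and cartilage genes were lower with anti-OSM. Dilution of deep ear tissue by soft tissue would lower adipocyte and nerve markers too. A scaling factor would move all genes of a library alike. The joint median of those 27 members lay 0.52 above that of 39 muscle and cartilage members (-0.06 against -0.58). The SE of 0.08 is over genes taken as independent and leaves out the spread between libraries, so it understates the error. Estimated correlations were 0.53 in muscle, 0.02 in cartilage, 0.43 in adipocyte and 0.15 in nerve markers. With that limit, the medians argue against either as the whole cause. Against that, 4 of 15 adipocyte markers were lower and 0 higher, and their list was called lower without anti-Ly6G replicate 1 (adjusted p = 0.0139), so a part stays open. Scaling with factors from genes outside the lists, the first test of this, moved the median of all genes by -0.00134 and so tested nothing. A difference in how much muscle and cartilage each piece held, and an effect of the antibodies, stay open and were not tested.

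The real split of the 6 libraries called 2406 genes and the highest of the other splits called 0. With 3 against 3 there are 10 splits, and only the real split called that many, so the share cannot go under 0.1. Every other split puts libraries of both groups in each set of 3. A difference between the groups then widens the spread within sets, so 0 calls there say little.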
